A study of Glycine max with 36 samples.

How the data were processed

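RNA from the pooled 3 leaflets of the first trifoliate leaf of soybean cultivar Williams 82 was compared on 36 two-colour cDNA arrays of 19200 probes each. Plants had been sprayed with the photosystem II inhibitors atrazine or bentazon at 22 to 25 mM, or with water containing 1% adjuvant, and were sampled 1, 2, 4 and 8 h later. The adjuvant is recorded here for the water spray only, and the dose range for both herbicides together. Whether the herbicide sprays held adjuvant, and which dose each had, is not known here. Effects of adjuvant or dose can thus not be told apart from those of the herbicides. The 12 RNA groups (3 treatments by 4 times) formed a closed loop of 12 direct comparisons, with 1 array for each of 3 biological replicates. As labelled, each RNA met the Cy3 dye once and the Cy5 dye once within a loop. Atrazine and water RNA shared an array at 2 and 4 h only, and bentazon and water RNA at 1 and 8 h only. The other comparisons of a herbicide with water ran through further RNAs of the loop and are less precise. The labels call the 3 repeats biological but do not say whether they came from separate sowings or days. They also speak of technical repeats with dye swaps, but each comparison appears in 1 orientation per biological replicate. Whether repeat arrays were averaged or left out is not known, and if they were averaged the dye term would not hold.

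The deposited table holds 1 log ratio per probe and array, taken here as log2. Per the labels' protocols, total RNA was extracted with Trizol and labelled indirectly through aminoallyl-dUTP. The log base, the numerator channel, the background correction and the normalization are not given in the sources used here. If the values were natural logs, each log2 size printed would be too small by a constant factor, and no test would change. Array means lay between -0.0183 and 0.00493 and array medians between -0.047 and 0.0464. Arrays held between 16648 and 18484 values. No intensities were used, so brightness and saturation of spots could not be weighed, and the number of arrays limits the precision.

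Of 19200 probes, 17062 had a value on at least 2 of the 3 arrays of each hybridisation type and were tested, 12843 had a value on every array and 555 had none. The probe annotation used here lists 1 gene for 1158 probes (527 genes, of which 523 were matched by gene ID to the Glycine_max_v4.0 gene table for current symbols), several genes for 13 probes, and none for the remaining 18029. Only 6.22% of the tested probes (1062) therefore carry a gene name here, and 780 carry a name that is more than a placeholder. A probe that is not listed is unnamed here, not without a gene. Probes are cDNAs, so transcripts of related family members can hybridise to the same spot.

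One linear model per probe was fitted to all 36 arrays with 11 RNA differences and 1 dye term, with exact contrasts for each pattern of missing values, and variances were moderated with limma 3.58.1 in R 4.3.3 (24 residual and 7.56 prior degrees of freedom). Probes were called at a Benjamini-Hochberg adjusted p of 0.05 per comparison, and adjusted p values below are from this limma model unless another test is named. Errors are standard errors of the model, and SDs are over the 3 estimates obtained by solving each replicate's loop alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

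The direction of the ratio was to be called only if 2 anchors agreed: evening against morning clock genes in water, and glutathione transferases under herbicide. There was 1 morning clock probe and 0 evening clock probes, so the first anchor could not be used, and no direction is called. The median of the 27 glutathione transferase probes in the mean herbicide effect was -0.109 as Cy5 over Cy3. Values are instead signed by 1 gene: the sign was set so that the PDR12 probe is positive under bentazon at 2 h. A positive value thus means the same side as PDR12 in bentazon, and a negative value the other side. Which side is higher expression is not known. PDR12 was chosen for this after its values were seen. In the differences between herbicides and between times the same sign applies, with the first-named group minus the second.

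The arrays were checked for a common orientation. Arrays of one type correlated between -0.29 and 0.79 over all probes, the only negative value lying between replicates 2 and 3 of the 1 h against 2 h water arrays. On the 200 probes with the largest mean ratio of each type, 33 of 36 arrays closed their loop more tightly as labelled than with the sign turned. The exceptions were replicates 1 and 3 of the 1 h against 2 h water comparison and replicate 2 of the 4 h against 8 h water comparison. No array was turned. Deviations from the type means of arrays with one replicate number and no shared RNA had a median correlation of 0.01, so the numbers were not treated as pairing samples beyond the shared RNA of each loop. Arrays that shared an RNA extract did covary, with an extract variance of 0.214 times the array variance by restricted maximum likelihood, and a generalised least squares fit with that covariance was an alternative.

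Gene lists (27 themes) were drawn up before the data were examined, as were the tests, the rule for named genes and most of the alternative settings. Because the annotation holds symbols only, the symbols of each list were assigned afterwards, before gene-level values were seen, except that 1 ambiguous symbol was taken out of the jasmonate and ethylene list after a first fit. Lists with at least 5 tested probes (20) were tested with limma's camera at each time. Since camera takes no missing values, its ranked-statistic form was run on z scores of the moderated t with a preset correlation of 0.01, and again with a correlation estimated from members with all values. A further 4 lists had fewer than 5 probes and were not tested, and the remaining lists were not tested either. The list tests for atrazine against bentazon and for water, and the comparisons of 8 h with 4 h, were added after a first fit. The lists without a call in either herbicide were chlorophyll synthesis, antioxidants, sugar starvation, defence proteins, drought and osmotic stress, cytosolic ribosome, cell wall growth, histones and cell cycle, senescence and proteolysis, nitrogen and amino acids, seed, and vascular tissue.

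Genes were named by rule: for each herbicide at each time, the 3 largest effects on each side among called probes with a gene name whose 3 single-loop estimates shared one sign, 1 probe per gene. The same applied to atrazine against bentazon at 8 h and to water at 8 h against 1 h. For each list with a call, the 2 members with the smallest adjusted p on each side at the time of the smallest list p were added. Symbols that are bare locus numbers without a synonym were treated as unnamed, a choice made after a first fit.

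Alternative settings were no dye term, an intercept for each replicate number, generalised least squares, each loop solved alone, arrays centred or scaled, array weights, a robust prior, wider and narrower probe filters, arrays that hold both groups alone, averages over probes of a gene name, the sign turned, and each replicate left out. Another 2 were chosen after seeing the data: leaving out the 4 h against 8 h water array of replicate 2, and leaving out the 3 water arrays of 1 h against 2 h together with the dye term.

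The model was tested on simulated data with the real probe spreads, 200 changed probes and shared RNA extracts, for atrazine against water at 8 h over 17062 probes. It recovered 31% of probes changed by 1 log2 unit and 92% of those changed by 2 units. Of its 130 calls, 5.38% were unchanged probes, and a comparison without changes gave 0 calls.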

Results

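The series followed the transcripts of soybean leaflets over 8 h after spraying with atrazine or bentazon, herbicides that both block electron transport at photosystem II but differ in chemical structure. A total of 17062 probes were tested in 3 biological replicates (n = 3 loops), of which 12843 had a value on every array. The others lacked at least 1 value, so that not all 3 loops were complete behind them. The comparisons address which transcripts responded to each herbicide and when. Values are log2 differences signed by the PDR12 probe, positive on the side that PDR12 took under bentazon, and they do not state whether a transcript was more or less abundant.

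Atrazine differed from water at every time. At 1 h, PM37, a DnaJ-type chaperone, had a value of 3.01 ± 0.609 (SE, adjusted p = 0.00425), on the side of PDR12 with UGD1, a UDP-glucose dehydrogenase (1.67), and HPS (1.66). STP (-2.56 ± 0.407, adjusted p = 0.00049), the omega-3 desaturase gene FAD3C (-2.07) and PK3 (-1.92) lay on the other side. At 2 h the largest named effects were those of XET1, which encodes a cell-wall xyloglucan endotransglycosylase (2.22), SARK, a senescence-associated receptor kinase (1.57), and LOC547791 (PK) (1.43) on the one side, and MIPS, the myo-inositol phosphate synthase (-2.32), COPZ1, a coatomer subunit (-1.76), and PK3 (-1.60) on the other. In all, 580 probes were called at 1 h (364 with PDR12 and 216 against) and 894 at 2 h (436 and 458). The share with PDR12 at 1 h was 62.8%, but 50.7% with array weights, 52.8% with each loop solved alone and 74.5% without replicate 1, and at 2 h it was 48.8%, but 68.1% without replicate 1. Without replicate 1, 2 or 3 the counts were 47, 108 and 356 at 1 h, and 47, 484 and 602 at 2 h. Without replicate 1 the calls of PM37, UGD1, HPS and PK3 at 1 h (adjusted p = 0.0914, 0.308, 0.116 and 0.144) and of SARK, LOC547791 (PK), MIPS, COPZ1 and PK3 at 2 h (0.537, 0.204, 0.088, 0.124 and 0.0712) were lost. Those of PM37, UGD1 and HPS were also lost without replicate 2 (0.101, 0.115 and 0.0758), and those of HPS and of PK3 at 1 and 2 h without replicate 3 (0.19, 0.0644 and 0.059). SARK lost its call with a robust prior too (0.0649). A lost call need not mean a smaller value. Without replicate 1 PM37, UGD1, HPS and PK3 stood at 3.02, 1.27, 1.79 and -1.84 at 1 h. SARK, LOC547791 (PK), MIPS, COPZ1 and PK3 then stood at 1.06, 1.25, -1.905, -1.735 and -1.61 at 2 h. The other SARK and LOC547791 (PK) probes lay on the other side at 2 h without a call, as did the other STP probe and 1 of the 2 other UGD1 probes at 1 h.

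By 4 h the atrazine effects had widened to 3059 probes, 1560 with PDR12 and 1499 against, and at 8 h 1995 probes were called (962 and 1033). Precision differed between times (median SE 0.213 at 4 h and 0.286 at 8 h), since atrazine and water shared an array at 4 h but not at 8 h. Calls of at least 1 log2 unit were 1139 at 4 h and 1417 at 8 h. The counts at these times are thus not on an equal footing. At 4 h XET1 stood at 3.09 ± 0.287 (adjusted p = 3.38e-09), the beta-amylase gene LOC547684 (BMY1) at 3.02 ± 0.528 and the pathogenesis-related gene PR-10 at 2.69 ± 0.628. On the other side were MIPS (-3.32 ± 0.373, adjusted p = 9.54e-08), COPZ1 (-3.16) and PK3 (-2.50). At 8 h PR-10 (3.92 ± 0.846, adjusted p = 0.00181), NOD33 (2.51) and the histone gene H4 (2.48) were opposed to MIPS (-3.73 ± 0.542), PK3 (-3.61) and the lipoxygenase gene LOC547835 (loxA) (-2.68). All 4 MIPS probes were called on one side at 2, 4 and 8 h, and all 6 LOC547835 (loxA) probes at 8 h, whereas 1 of the 5 H4 probes went the other way without a call. Without replicate 1, 896 probes were called at 4 h and 655 at 8 h, and without replicate 2, 1549 and 831. The call of H4 was lost without replicate 2 (adjusted p = 0.0656), and with each loop solved alone 1256 probes were called at 8 h.

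PDR12, an ABC transporter of the pleiotropic drug resistance type, differed from water by 4.00 ± 0.436 at 1 h, 5.86 ± 0.587 at 2 h and 5.24 ± 0.587 at 4 h (adjusted p = 1.83e-07, 5.31e-08 and 3.25e-07), and by 1.17 at 8 h, which was not called (adjusted p = 0.0621). Its sign at 2 h is positive by construction. The glutathione transferase gene GSTL3 moved with it at 3.04, 4.41, 4.46 and 2.73 in time order, each called, and GSTU30 at 3.10 at 1 h. SARK reached 4.39 ± 0.612 at 2 h and 4.53 ± 0.612 at 4 h. The second GSTL3 probe and both other GSTU30 probes were not called at any of these times, and at 4 h another SARK probe was called on the opposite side. On the side against PDR12 the 1 h effects were smaller: NAC6 (-1.12), the phenylpropanoid gene 4CL4 (-0.93) and SCA2 (-0.62). At 2 h PK3 (-1.78), the methionine pathway gene CGS2 (-1.78) and PRX2B (-1.64) were largest there. Bentazon gave 571 calls at 1 h (422 with PDR12 and 149 against) and 1293 at 2 h (809 and 484), of which 338 and 1010 were of at least 1 log2 unit. The share with PDR12 at 1 h was 73.9%, but 56.6% with array weights and 95% without replicate 1. Without replicate 1 the counts were 119 and 308, without replicate 2 they were 540 and 621, and without replicate 3 they were 370 and 989. The calls of 4CL4 and SCA2 were lost without any one of replicates 1, 2 and 3 (adjusted p = 0.104, 0.0634 and 0.167, and 0.137, 0.351 and 0.0973), those of NAC6 and of PK3 at 2 h without replicate 1 (0.568 and 0.127) or 3 (0.177 and 0.116), and that of CGS2 without replicate 1 (0.0675). At 2 h 1 of the 2 other PK3 probes and 2 of the 4 other CGS2 probes lay on the opposite side without a call. The share with PDR12 at 2 h was 62.6%, but 81.8% without replicate 1.

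At 4 h bentazon gave 2287 calls (1193 with PDR12 and 1094 against) and at 8 h 2774 (1506 and 1268). Calls of at least 1 log2 unit were 1563 at 4 h (835 with PDR12 and 728 against) and 832 at 8 h (326 and 506). The majority at 8 h thus turned with this minimum size. The median SE was 0.287 at 4 h and 0.211 at 8 h, where bentazon and water shared an array. The share with PDR12 at 4 h was 52.2%, but 70.5% without replicate 1. VPE2, a vacuolar processing enzyme, was at -3.88 ± 1.17 at 4 h (adjusted p = 0.0249) and -3.45 ± 0.871 at 8 h, and COPZ1 (-2.84) and PK3 (-2.73) were the next largest on that side at 4 h. At 8 h GSTL3 (2.73), SRC1 (2.19) and DREB1-like (2.14) were opposed to VPE2, PK3 (-2.27) and CYP93E1, a triterpenoid hydroxylase (-2.22 ± 0.267, adjusted p = 2.75e-06). All 3 CYP93E1 probes were called, while the other 3 DREB1-like probes lay on the opposite side without a call. The calls of VPE2 were lost without replicate 1 (adjusted p = 0.241 at 4 h and 0.16 at 8 h) or 2 (0.0846 and 0.071), and at 4 h also with scaled arrays (0.0616) and a robust prior (0.0552). Without replicate 1 the counts were 342 and 631, and without replicate 2 they were 1075 and 620.

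**Figure D1:**
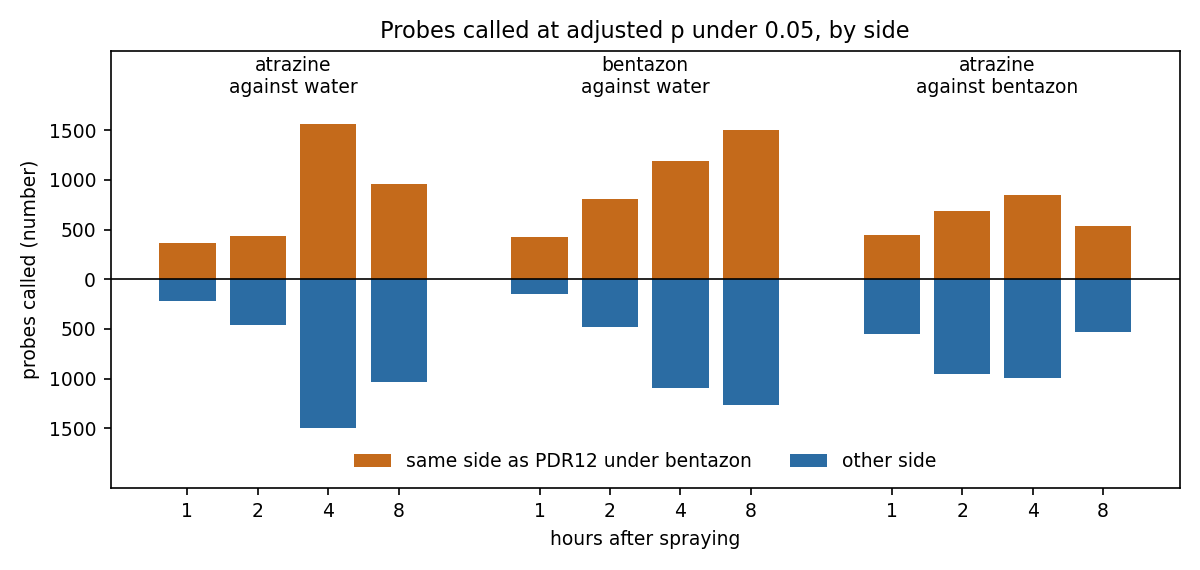
Number of probes called at adjusted p under 0.05 (vertical axis) at 1, 2, 4 and 8 h after spraying (horizontal axis) for each comparison, above 0 for the side of PDR12 under bentazon and below 0 for the other. Atrazine has 1560 and 1499 at 4 h and bentazon 1506 and 1268 at 8 h, but the standard errors differ between times and with a minimum size of 1 log2 unit most calls are at 8 h for atrazine (1417) and at 4 h for bentazon (1563).

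At 4 h 1329 probes were called for both, of which 584 lay with PDR12 in both, 737 against it in both and 8 on opposite sides. Independent lists of these sizes would share 109 and 96.1. At 8 h the counts were 500, 681 and 2, against 84.9 and 76.8. Those values leave out the shared water RNA, which by itself puts calls on one side, so the excess over them does not show a shared effect. The correlation across probes, which are not independent, was 0.577 at 1 h, 0.603 at 2 h, 0.72 at 4 h and 0.755 at 8 h, against 0.624, 0.626, 0.626 and 0.623 in simulated data without effects. At 1 and 2 h it was thus no larger than in these simulated data, which hold the error of arrays and RNA extracts. Effects particular to 1 herbicide lower a correlation, so this does not exclude a shared effect. The covariance was larger than simulated at each time (0.121, 0.157, 0.313 and 0.271, against 0.0496, 0.0499, 0.0501 and 0.0494). At 4 and 8 h the correlation was larger than simulated as well. For these times the values argue against error in the shared water RNA as the only source of the agreement. The spread of the simulated values is not given. How many of the shared calls the shared water RNA gives was not tested.

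The herbicides also differed from each other at every time. PDR12 separated them by -3.95 ± 0.436 at 1 h, -5.82 at 2 h and -4.64 at 4 h (atrazine minus bentazon, adjusted p = 3.01e-07, 6.61e-11 and 4.63e-09), but not detectably at 8 h (-0.71, adjusted p = 0.383). GSTL3 differed at all 4 times, by -2.91, -4.21, -4.04 and -2.83. XET1 differed the other way, by 1.55, 1.90, 1.42 and 1.13. At 8 h the largest named differences were PR-10 (2.73 ± 0.628, adjusted p = 0.00637), MMP2 (2.39) and H4 (2.37) on one side and GSTL3, MIPS (-2.16) and GSTU30 (-1.66) on the other. In total 997, 1641, 1849 and 1066 probes differed at 1, 2, 4 and 8 h. The count at 8 h was not kept in every setting: 0 probes were called by limma on the 3 loops solved alone (2359 at an unadjusted p under 0.05), and 0 on the 3 direct arrays (2713 unadjusted), and none of the 6 named calls at 8 h held there. Both other GSTU30 probes lay on the opposite side without a call. At 1 and 4 h the loops solved alone gave 233 and 271 calls. Without replicate 1 the counts were 331, 519, 405 and 277, without replicate 2 they were 216, 808, 902 and 552, and without replicate 3 that at 8 h was 673. At 8 h the calls of PR-10, MMP2, MIPS and GSTU30 were lost without replicate 1 (adjusted p = 0.108, 0.0814, 0.11 and 0.167), that of GSTU30 without replicate 2 (0.185), and those of PR-10 and MMP2 without replicate 3 (0.159 and 0.184).

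**Figure D2:**
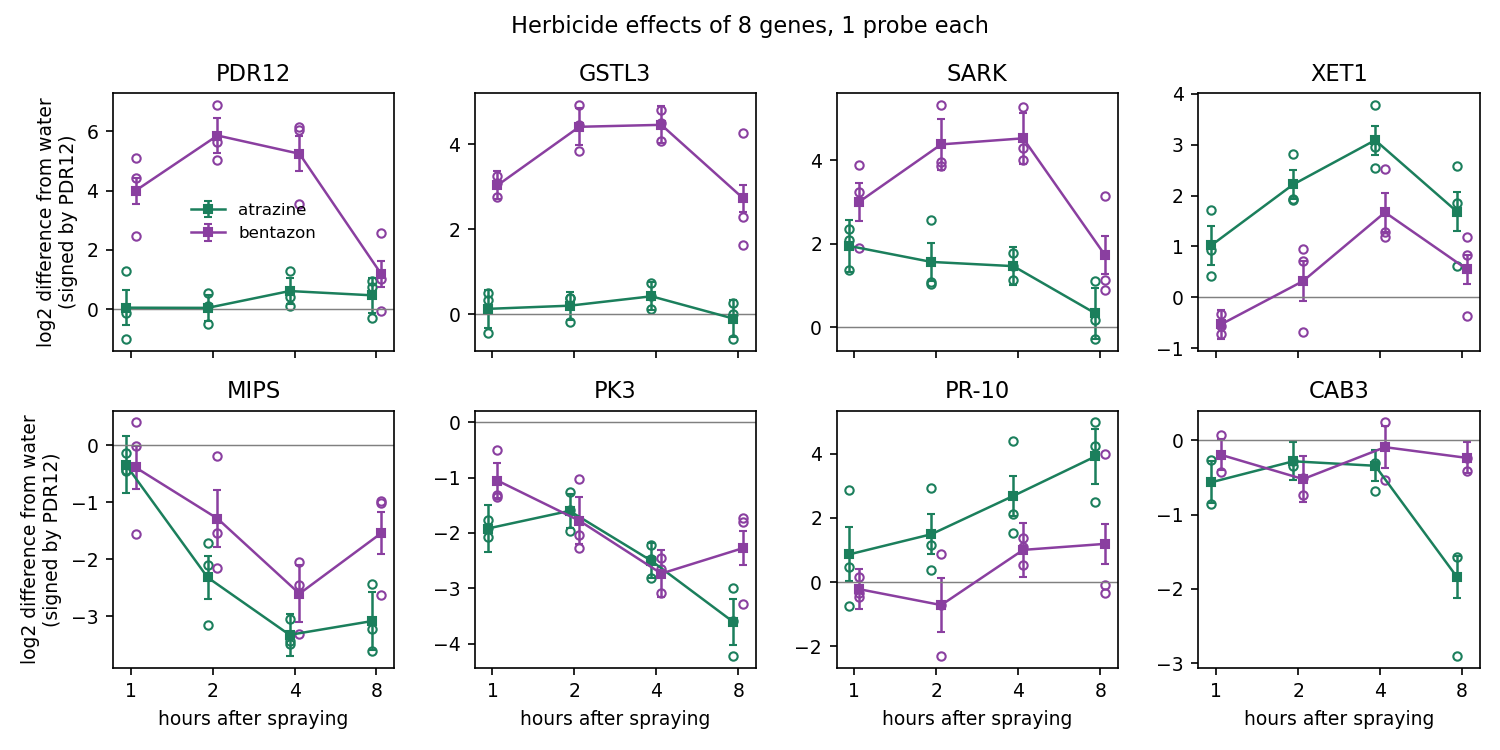
Log2 difference from water, signed by PDR12 (vertical axes, each with its own range), against hours after spraying for 8 genes, 1 probe each. Squares with bars are the model value ± SE and open circles the 3 replicate loops where complete; PDR12 under bentazon peaks at 5.86 at 2 h while atrazine stays between 0.04 and 0.61.

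Among photosynthesis genes the difference lay in CAB3, which encodes a chlorophyll a/b-binding protein of the light-harvesting antenna. At 8 h 5 of its 6 probes were called for atrazine against water (median of 6 probes -1.73) and 0 for bentazon by limma (median -0.151, from -0.496 to 0.0694), and 5 of 6 differed between the herbicides (median -1.54), though 0 of 6 did so with each loop solved alone (median -1.54). The named probe stood at -1.84 ± 0.284 (adjusted p = 4.07e-05). The list of light reactions, 10 probes of 3 genes, was called for atrazine at 8 h (5 against PDR12, 0 with it, 5 not called; adjusted over the list alone 5 and 1, median -0.83, adjusted p = 0.00392). It was not called with an estimated correlation (adjusted p = 0.526). Its other genes were not called: LOC547819 (LHCP) was at 0.31, and the PSAD probes disagreed in sign (0.86 and -0.25), the former passing without replicate 3 (adjusted p = 0.0205) and with array weights (0.00158).

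Glutathione transferases, which conjugate electrophiles to glutathione, were called as a list under bentazon. Of 27 glutathione transferase probes, 4 were called with PDR12 and 0 against at 1 h, 5 and 0 at 2 h, and 6 and 1 at 4 h (adjusted over the list alone 4 and 1, 5 and 0, and 8 and 3), and 23, 22 and 20 were not called. The medians were 0.14, 0.31 and 0.24. The list passed at these times (adjusted p = 0.00634, 0.00634 and 0.0391) but not with an estimated correlation (adjusted p = 0.393, 0.393 and 0.628). It did not pass at 8 h (5 with PDR12, 1 against, median 0.11, adjusted p = 0.537) or under atrazine at any time (smallest adjusted p = 0.343; 2 with and 4 against at 4 h). Members without a call at 1 h were LOC547581 (GSTU21) (-0.66, called with scaled arrays at an adjusted p of 0.0102 and with array weights at 0.00364) and GSTU41 (-0.19). All 3 other LOC547581 (GSTU21) probes lay on the opposite side without a call. Atrazine minus bentazon was called for the list at 2 and 4 h (adjusted p = 7.54e-06 and 0.00276; 0.067 and 0.217 with an estimated correlation). The 7 glycosyltransferase probes were called for atrazine at 2 and 4 h (2 and 3 probes with PDR12, 0 against, 5 and 4 not called; adjusted over the list alone 4 and 4; medians 0.54 and 0.63, adjusted p = 0.00535 and 0.0449; 0.377 and 0.771 with an estimated correlation). Under bentazon they did not pass (smallest adjusted p = 0.0522, at 1 h), and at 8 h 0 lay with PDR12 and 3 against (median -0.66, adjusted p = 0.167). Their examples were UGT1 (0.77 ± 0.214) and LOC732565 (SGT3) (1.01 ± 0.306), which lost their calls without replicate 1 (adjusted p = 0.207 and 0.194), 2 (0.182 and 0.271) or 3 (0.09 and 0.143). LOC732565 (SGT3) also lost its call with an intercept for each replicate number (0.0522) and with generalised least squares (0.0541). Of 22 cytochrome P450 probes 6 lay against PDR12 and 2 with it under bentazon at 8 h (14 not called; adjusted over the list alone 6 and 2, median -0.64, adjusted p = 0.009; 0.628 with an estimated correlation), among them CYP93E1, the allene oxide synthase AOS1 (-1.29) and, with PDR12, CYP97B2 (adjusted p = 0.000671). The probe of CYP98A2 at 0.44 was not called, and another of its probes was called on the other side. Of the 2 other CYP97B2 probes 1 was opposite in sign without a call. AOS1 lost its call without replicate 2 (adjusted p = 0.064).

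Probes of phenylpropanoid genes and of jasmonate and ethylene genes that were called at 8 h lay mostly against PDR12 under both herbicides. The phenylpropanoid list held 84 probes of 23 genes and the other 44 probes of 14 genes, so counts of probes are not counts of genes. Of 84 phenylpropanoid probes, 19 were called against PDR12 and 2 with it for atrazine at 8 h, and 17 and 3 for bentazon (63 and 64 not called; adjusted over the list alone 23 and 2, and 17 and 3; medians -0.19 and -0.35, adjusted p = 0.00142 and 2.27e-05; 0.771 and 0.393 with an estimated correlation). The flavonoid gene F3H (-1.57 ± 0.282), with 8 of 9 probes called for bentazon at 8 h, and 4CL4 (-1.54 ± 0.223) were examples, and CHR1 (0.97) and DFR1 (0.65) lay on the other side. Of the other probes, 1 of 2 for 4CL4 and 2 of 4 for CHR1 were opposite in sign without a call. F3H alone gave 7 of the atrazine calls against PDR12 at 8 h and 8 of the bentazon calls. CHR1 and DFR1 lost their calls with scaled arrays (adjusted p = 0.0817 and 0.0567) and without replicate 1 (0.126 and 0.145) or 2 (0.32 and 0.189), and DFR1 without replicate 3 (0.0523). The list also passed at 1 and 4 h for atrazine (adjusted p = 0.0306 and 0.0215; 0.804 and 0.804 with an estimated correlation) and at 4 h for bentazon (adjusted p = 0.00285; 0.628 with an estimated correlation). Of 44 jasmonate and ethylene probes, 18 lay against PDR12 and 2 with it for atrazine at 8 h, and 14 and 2 for bentazon (24 and 28 not called; adjusted over the list alone 22 and 2, and 16 and 2; medians -0.79 and -0.43, adjusted p = 4.03e-06 and 0.000358; 0.377 and 0.602 with an estimated correlation). Lipoxygenases made up its examples: LOC547835 (loxA) (-2.51 ± 0.416), VLXC (-1.60) and, on the other side, VLXB (1.71), together with the jasmonate receptor gene COI1 (1.05). The other VLXB probes lay on the opposite side without a call. LOC547835 (loxA) gave 6 of the atrazine calls against PDR12 at 8 h and 5 of the bentazon calls, and VLXC 2 and 2. VLXB and COI1 lost their calls without replicate 1 (adjusted p = 0.146 and 0.0641) or 2 (0.0587 and 0.189), and COI1 without replicate 3 (0.059). The list passed at 4 h for both herbicides too (adjusted p = 0.0109 and 0.00634; 0.804 and 0.703 with an estimated correlation).

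The heat shock protein list passed on the side of PDR12 at 1, 2 and 4 h, but not at 8 h for atrazine or bentazon (adjusted p = 0.343 and 0.883). Of its 10 probes 3 were called with PDR12 and 0 against for atrazine at 1 h, and 4 and 0 for bentazon at 4 h (7 and 6 not called; adjusted over the list alone 4 and 0, and 5 and 0; medians 0.47 and 0.65, adjusted p = 0.00126 and 0.00684; 0.0692 and 0.393 with an estimated correlation). Every atrazine call at 1 h was a PM37 probe (3 of 5 probes called), as were 2 of 2 bentazon calls at 1 h, 3 of 3 at 2 h and 3 of 4 at 4 h, and both named PM37 probes lost the call without replicate 1 (adjusted p = 0.0914 and 0.0886). The chaperone gene BIP4 was at 0.74 and -0.05 in 2 of its 3 probes, neither called. The list passed at 2 and 4 h for atrazine (adjusted p = 0.042 and 0.0248; 0.377 and 0.345 with an estimated correlation) and at 1 and 2 h for bentazon (adjusted p = 0.0106 and 0.00684; 0.393 and 0.393 with an estimated correlation). The nodule and root list of 7 probes, included for transcripts of other organs, passed for atrazine at 8 h (4 with PDR12, 0 against, 3 not called; adjusted over the list alone 4 and 0, median 0.93, adjusted p = 0.0109; 0.0679 with an estimated correlation), with NOD33 (2.51 ± 0.412) and ENOD40B (0.93) on one side and UR9 (-0.36, not called) on the other. ENOD40B lost its call without replicate 1 (adjusted p = 0.153) or 2 (0.137).

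The other 12 lists did not pass against water, and each is given at its smallest adjusted p unless stated. Cell wall growth genes came nearest, under atrazine at 2 h (2 with PDR12, 0 against and 10 not called; adjusted over the list alone 3 and 0, median 0.20, adjusted p = 0.0587). At 8 h that list had 2, 4 and 6 under atrazine (median -0.14, adjusted p = 0.562) and 0, 4 and 8 under bentazon (median -0.26, adjusted p = 0.177). Cytosolic ribosome genes followed under atrazine at 4 h (0, 1 and 8; list alone 0 and 0, median -0.33, adjusted p = 0.0733), but had 5, 0 and 4 under bentazon at 8 h (list alone 5 and 0, median 0.55, adjusted p = 0.116). Nitrogen and amino acid genes had 2, 0 and 9 under atrazine at 8 h (list alone 2 and 0, median 0.26, adjusted p = 0.142), seed genes 3, 0 and 35 under bentazon at 1 h (list alone 3 and 0, median 0.03, adjusted p = 0.167) and vascular genes 0, 1 and 9 under bentazon at 8 h (list alone 0 and 1, median -0.75, adjusted p = 0.167). Sugar starvation genes had 1, 0 and 10 under bentazon at 4 h (list alone 1 and 0, median 0.26, adjusted p = 0.22), histone and cell cycle genes 0, 2 and 6 under bentazon at 8 h (list alone 0 and 2, median -0.15, adjusted p = 0.299) but 4, 1 and 3 under atrazine at 8 h (list alone 4 and 1, median 0.99, adjusted p = 0.482) and drought genes 1, 1 and 14 under bentazon at 2 h (list alone 1 and 1, median -0.31, adjusted p = 0.367). Antioxidant genes had 0, 4 and 17 under atrazine at 2 h (list alone 3 and 6, median -0.08, adjusted p = 0.415), chlorophyll synthesis genes 0, 1 and 4 under atrazine at 8 h (list alone 0 and 1, median -0.19, adjusted p = 0.482), and senescence genes 1, 0 and 20 under atrazine at 2 h, with a median of -0.02 against a mean of 0.10 and a test on the side of PDR12 (list alone 1 and 0, adjusted p = 0.562). Defence proteins, given under atrazine at 8 h, had 2, 1 and 14, with a median of -0.01 against a mean of 0.35 and a test on the side of PDR12 (list alone 2 and 1, adjusted p = 0.713). Of 80 tests of 20 lists at 4 times per herbicide, 12 passed for atrazine and 11 for bentazon. With an estimated correlation camera gave 0 and 0, and with probes averaged by gene 1 and 5. In a test with herbicide and water labels swapped at random, 24 of 100 labellings, the real one included, gave at least as many atrazine lists as its 13.

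**Figure D3:**
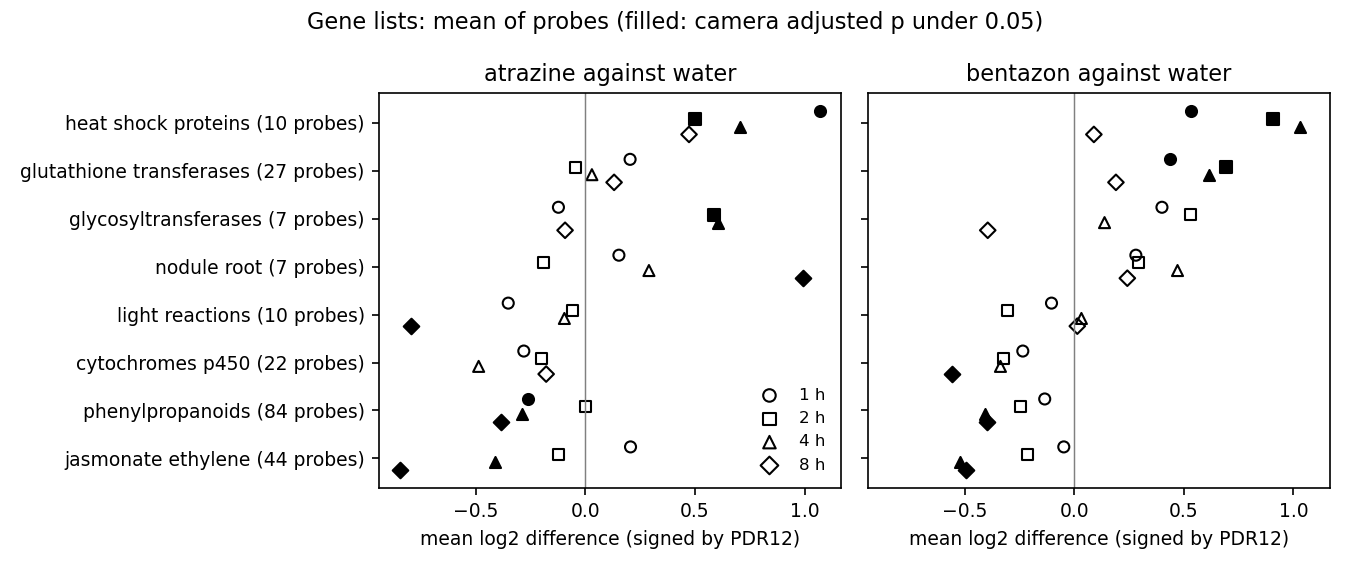
Mean log2 difference from water over the probes of 8 gene lists (horizontal axis, signed by PDR12) at 4 times (symbols), for each herbicide. Filled symbols passed camera with a preset correlation; the jasmonate and ethylene list has the lowest mean under atrazine at 8 h (-0.844) and the heat shock list the highest at 1 h (1.07).

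Averaged over the 4 times, atrazine differed from water at 4467 probes (2242 with PDR12 and 2225 against) and bentazon at 4509 (2126 and 2383). The effect of atrazine differed between times at 409 probes and that of bentazon at 580 by the F test. Without replicate 1 none was called by limma (1604 and 1328 at an unadjusted p under 0.05), without replicate 2 the counts were 12 and 116, and without replicate 3 that of atrazine was 256. The mean effects gave 1808 and 1824 calls without replicate 1, and 2827 and 2633 without replicate 2.

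In water alone, 8 h differed from 1 h at 287 probes (113 with PDR12 and 174 against), and at 764 with generalised least squares, 1667 with array weights and 1771 with each loop solved alone. The share with PDR12 was 39.4%, but 60.5% without replicate 3 (46 of 76) and 29% without replicate 2. ELIP, an early light-induced protein of the chloroplast, had the largest named value (-3.08 ± 0.508, adjusted p = 0.00243), followed on that side by MYB138 (-2.22) and CGS2 (-2.06). On the other side were LOC547791 (PK) (2.42), DREB1-like (2.26) and ALDH7B1 (1.79), the last an aldehyde dehydrogenase. Of the other probes, 1 of 3 for DREB1-like, 2 of 3 for ALDH7B1 and 1 of 4 for CGS2 lay on the opposite side without a call. No water group at 2 or 4 h differed from 1 h by limma (0 and 0 probes, with 628 and 855 at an unadjusted p under 0.05). Without replicate 1 the count at 8 h was 0 by limma (1119 at an unadjusted p under 0.05) and none of the 6 named calls held (adjusted p from 0.36 to 0.745). Without replicate 2 it was 214 and LOC547791 (PK) lost its call (adjusted p = 0.0814), and without replicate 3 it was 76 and DREB1-like, ALDH7B1 and MYB138 lost theirs (0.174, 0.0848 and 0.155). It was 168 without the 4 h against 8 h water array of replicate 2, where DREB1-like and MYB138 lost their calls (0.0555 and 0.0694), and 14 without the 1 h against 2 h water arrays and the dye term. Both of the latter fits were chosen after seeing the data, and in the second none of the 6 named calls held, with ELIP at an adjusted p of 0.05. DREB1-like lost its call with scaled arrays as well (0.0559).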

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

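No test of an explanation in this part was chosen after the result was seen, but the comparisons of 8 h with 4 h were added after a first fit. The effect of a herbicide differed between times at 409 probes for atrazine and 580 for bentazon, by an F test on the differences between times. The times were permuted within replicates, in the same order for every treatment of a replicate. Of 100 splits, the real one included, 3 reached the real count for atrazine (386 real, 489 the highest other). For bentazon 1 of 100 did (551 real, 391 the highest other). These splits also scrambled any time course that the treatments share, so they cannot tell whether chance gave the counts. For this test the model was fitted to the 12843 probes with a value on every array.

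Between 4 and 8 h the effect of atrazine differed at 7 probes and that of bentazon at 250, by the test of the difference. Of the 250, 229 were smaller in size at 8 h, 21 were larger and 102 lay on the other side. The difference between atrazine and bentazon itself changed between 4 and 8 h at 499 probes. The comparisons of 8 h with 4 h were not run in the other settings. Without replicate 1 the F test on differences between times gave 0 calls for each herbicide. Bentazon against water was less precise at 4 h than at 8 h (median SE 0.287 and 0.211). Probes picked for a difference can thus have values at 4 h that are too large. The glycosyltransferase gene UGT1 was called on opposite sides under bentazon, at 0.99 at 2 h (adjusted p = 0.0286) and -0.67 at 8 h (adjusted p = 0.031), and its effect differed between times (adjusted p = 0.0177). With groups of 3, no single sample was tested for lying apart.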

How the results depend on the processing

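The fits without the 4 h against 8 h water array of replicate 2, and without the 1 h against 2 h water arrays and the dye term, were chosen after seeing the data. Counts within 1.5 times the reported one are not listed. With the sign turned every count stays the same by construction, so that setting tests nothing. No count of probes left the range of 1.5 times without a dye term, with arrays centred on the median, a robust prior, or wider or narrower probe filters. The same held with a replicate block, a separate intercept for each replicate number (for example 208 for water at 8 h against 1 h, and 317 and 425 probes differing between times under atrazine and bentazon). The gene lists were run among these only without a dye term and with the replicate block, which gave 12 for each herbicide with the block. For bentazon, more probes were called at 4 h than at 8 h with generalised least squares (2837 and 2626), array weights (4311 and 3863), each loop solved alone (1958 and 1504), without replicate 2 (1075 and 620) and without replicate 3 (2519 and 2451).

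Array weights gave 1815, 2099, 5241 and 4714 probes for atrazine against water at 1, 2, 4 and 8 h, 1828, 2026 and 4311 for bentazon at 1, 2 and 4 h, 2226, 4219 and 4729 for atrazine against bentazon at 1, 4 and 8 h, 1667 for water at 8 h against 1 h, 7014 for the mean atrazine effect, and 2760 and 3155 for differences between times under atrazine and bentazon. The median weights of replicates 1, 2 and 3 were 1.36, 0.788 and 0.735. Arrays scaled to one spread gave 1076 and 1093 for atrazine and bentazon at 1 h, 149 for water and 217 for differences between times under atrazine. Each loop solved alone gave 1748 and 1256 for atrazine at 1 and 8 h, 2072 and 1504 for bentazon at 2 and 8 h, 233, 271 and 0 for atrazine against bentazon at 1, 4 and 8 h (2359 at an unadjusted p under 0.05 for the 0, by limma), 1771 for water and 994 for differences between times under atrazine. Generalised least squares gave 875 for atrazine at 1 h and 764 for water. Arrays that hold both groups gave 1502 for bentazon at 8 h, and 286, 347 and 0 for atrazine against bentazon at 1, 4 and 8 h (2713 unadjusted for the 0, by limma). Without the 1 h against 2 h water arrays and the dye term, 14 probes were called for water, and without the 4 h against 8 h water array of replicate 2, 168. Of the gene lists 0 and 0 passed for atrazine and bentazon with an estimated correlation, and 1 and 5 with probes averaged by gene. The cause of these shifts was not tested.

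Leaving out 1 replicate, or the 4 h against 8 h water array of replicate 2, gave 47 to 616, 47 to 914, 896 to 3230 and 655 to 2056 probes for atrazine at 1, 2, 4 and 8 h, and 119 to 564, 308 to 1297, 342 to 2519 and 620 to 2781 for bentazon. It gave 216 to 1494, 519 to 1654, 405 to 1930 and 277 to 1052 for atrazine against bentazon, 0 to 214 for water, 1808 to 4521 and 1824 to 4559 for the mean effects, 0 to 419 and 0 to 680 for differences between times, and 9 to 12 and 8 to 12 for the gene lists. The highest counts without 1 whole replicate were 356, 602, 3157 and 2056 for atrazine, 540, 989, 2519 and 2451 for bentazon, 1494, 1452, 1930 and 673 for atrazine against bentazon, 4311 and 4164 for the mean effects, and 256 and 609 for differences between times. Where 0 probes were called by limma, 1119 for water, 1604 for atrazine and 1328 for bentazon passed at an unadjusted p under 0.05. Fewer arrays give less power, but leaving out any replicate removed the same number of arrays, 12. Differences between times under bentazon were called at 0, 116 and 609 probes without replicates 1, 2 and 3, against 580 with all. Under atrazine they were called at 0, 12 and 256, against 409. The number of arrays alone thus does not account for the spread between these fits. Replicate 1 had the highest median array weight (1.36, against 0.788 and 0.735 for replicates 2 and 3), so by that measure its arrays varied least about the model. Whether this accounts for the lower counts without it was not tested.

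Of the named gene comparisons that were called, 34, 18 and 16 lost their call without replicates 1, 2 and 3, 11 with each loop solved alone, and 10 with arrays that hold both groups, a setting in which not every comparison could be made. With each loop solved alone these were the 6 genes of atrazine against bentazon at 8 h, SCA2, CHR1, DFR1, COI1 and ENOD40B (adjusted p from 0.0558 to 0.24), and with arrays that hold both groups those 6, LOC732565 (SGT3), SCA2, CHR1 and DFR1 (0.0569 to 0.245). DFR1 lost its call without a dye term (0.0547) and CHR1 with array weights (0.0576). Losing a call did not always go with a smaller value. Without replicate 1 VPE2 under bentazon at 4 h stood at -3.96, against -3.88 with all arrays. NAC6 under bentazon at 1 h did shrink there, to -0.73 from -1.12. Without the 1 h against 2 h water arrays and the dye term, PK3 at 1 h (0.0766), SARK at 2 h (0.0832), SCA2 (0.0574), LOC732565 (SGT3) (0.105) and DFR1 (0.172) lost theirs besides the 6 genes of water. Reversals were of uncalled values near 0: PSAD under atrazine at 8 h (0.008875 with each loop solved alone, and from -0.4137 to 0.008875 without 1 replicate) and BIP4 under atrazine at 1 h (from -0.3086 to 0.09551 without 1 replicate, and 0.07553 without replicate 3). Signal over background was not known, so no limit from spot brightness is given, and 3 replicates limit the precision of each value.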

Other observations

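The tests of glutathione transferase sides and of the 4 h against 8 h water array, the list tests below and the choice of LOC547643 and of CAB3 came after the values were seen, whereas the splits of the samples did not. The 3 tests of CAB3 were set after its difference had been seen, but before the values of these tests were. Atrazine minus bentazon separated further gene groups. The histone and cell cycle list lay on the side of PDR12 at 4 h (4 of 8 probes called, 0 against; adjusted p = 0.0123; 0.472 with an estimated correlation) and 8 h (4 and 0; adjusted p = 0.00383; 0.379 with an estimated correlation), where all of the called probes were those of H4. The nodule and root list did so at 8 h (3 of 7 probes, 0 against; adjusted p = 0.00383; 0.0142 with an estimated correlation), where all 3 called probes were those of NOD33, and the cell wall list at 2 h through XET1 and CEL12 (4 of 12, 0 against; adjusted p = 0.0133; 0.0328 with an estimated correlation). Cytosolic ribosome genes lay on the other side at 4 h (4 of 9 probes, 0 with PDR12; adjusted p = 0.00383; 0.138 with an estimated correlation), and light reactions at 8 h through CAB3 alone (5 of 10, 0 with PDR12; adjusted p = 3.13e-06; 0.0927 with an estimated correlation). Further lists passed with the preset correlation but not with an estimated one, and both adjusted p values are given in that order. Jasmonate and ethylene passed with PDR12 at 1 h (0 of 44 probes called by limma, adjusted p = 0.0215 and 0.685) and against it at 8 h (10 against and 1 with, adjusted p = 0.00997 and 0.652). Glycosyltransferases passed against it at 1 h (3 of 7, adjusted p = 0.0205 and 0.469). Phenylpropanoids passed with it at 2 h (9 of 84, adjusted p = 0.0241 and 0.695), cytochromes P450 at 8 h (0 of 22 by limma, adjusted p = 0.0303 and 0.652) and cell wall growth at 4 h (4 of 12, adjusted p = 0.0351 and 0.0778). In water, the jasmonate and ethylene list (0 of 44 probes called by limma; median 0.55; adjusted p = 0.0103; 0.688 with an estimated correlation) and the ribosome list (0 of 9 called; median 0.51; adjusted p = 0.0271; 0.688 with an estimated correlation) passed on the side of PDR12 at 8 h against 1 h.

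LOC547643, a placeholder name with 10 probes, had 6 probes called at 8 h under each herbicide (medians -2.92 for atrazine and -1.89 for bentazon), and 6 differed between the herbicides (median -0.99). Among unnamed probes called with one sign in all 3 loops, values under atrazine at 4 h reached 4.93 ± 0.605 and -4.60 ± 0.476, and under bentazon at 8 h 3.48 ± 0.624 and -6.02 ± 1.57.

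CAB3 differed between atrazine and bentazon at 8 h, with a median of -1.54 over 6 probes. The tables argue against a single replicate as the source of the sign, since the smallest median without 1 replicate was -1.03. They argue against the spread of the arrays too, since the median was -1.47 with scaled arrays. The size leaned on replicate 3, whose omission gave the -1.03, and with array weights the median was -1 (6 of 6 probes called). On 3 of 3 direct arrays of atrazine against bentazon the median had that sign (-0.92, -1.19 and -2.50). Those arrays carry most of the estimate, so that this adds little to it. Whether the treatment acted on this gene stays open, since the 6 probes can share signal with related genes, which was not tested. With each loop solved alone 0 of 6 probes were called by limma.

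Under bentazon the called glutathione transferase probes lay mostly with PDR12, and one candidate explanation is that the ratios run Cy3 over Cy5, so that this side is the higher one. The sides of these probes did not differ detectably from those of other called probes (smallest of 4 Fisher's exact p, two-sided, 0.127). Sides are counted relative to PDR12 whichever channel is the numerator, so this test cannot bear on the direction, which stays open. The loop of replicate 2 closed less tightly with its 4 h against 8 h water array as labelled. A turned array is argued against by its correlations over all probes with the other arrays of its type, the lower of which was 0.43.

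For 3 samples against 3 there are 10 splits, too few for a share under 0.05, and the real split was the 1 with the most calls. These were made on the levels solved from each loop alone. For atrazine at 1, 2, 4 and 8 h the real counts were 1036, 188, 790 and 1302, for bentazon 145, 1496, 1578 and 764, for atrazine against bentazon 92, 606, 171 and 15, and for water at 8 h against 1 h 2757, with 0 by limma as the highest other each time. The swaps of labels were made on the arrays, with the model fitted to the 12843 probes with every value. Herbicide and water labels were swapped at random within time and replicate. For the mean effect of atrazine 1 of 100 was as large, the real one included (3925 real, 3365 the highest other). For that of bentazon it was 1 of 100 too (3876 and 2395). No swap thus reached the real counts. The swaps treated the times of a replicate as separate units, though there were 3 biological replicates. They therefore cannot exclude chance differences between whole replicates. For the bentazon gene lists the swaps gave 2 of 100 as large (12 real, 12 the highest other). Swapped labels thus seldom reached that count, but another labelling equalled it and 0 of these lists passed camera with an estimated correlation. For the atrazine gene lists the swaps gave 24 of 100 (13 and 20), so chance cannot be excluded. Swapped labels keep part of the real effect.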
